A study of Mus musculus with 11 samples.

How the data were processed

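Enhanced reduced representation bisulfite sequencing was used to measure DNA methylation in blood progenitors of C57BL/6 mice. Genomic DNA was digested with MspI, fragments of 150 to 400 bp were bisulfite-converted and amplified, and single-end reads of 50 bp were made on a HiSeq2500, per the labels' protocols. The mice carried a floxed Dnmt3a gene with or without the Mx1-Cre transgene, received 5 injections of poly(I:C) and were 12 months old. Lin- Sca1+ cKit+ cells (LSK, the fraction that holds the stem cells) and Lin- Sca1- cKit+ CD34+ FcgR+ cells (GMP, the granulocyte-macrophage progenitors) were sorted from bone marrow.

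Each deposited table lists C positions of CpG sites with their coverage, a count of reads, and the percent of reads with C and with T, per the file headers. The submitters' processing notes name Bismark and the builds mm10 and GRCm38, without a version or a role. Every listed position had a coverage of at least 10, so positions with fewer reads are unlisted, and a missing position is not a count of 0. Methylated and unmethylated reads were recovered as coverage times the deposited percent. All of these products were whole numbers within the rounding of the 3 decimals of the percent columns. The 2 strands of a CpG are listed as separate C positions and were tested as such. Mitochondrial positions, 32 to 59 per library, were left out.

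Groups were taken from titles and genotype fields. They gave 3 control and 3 knockout LSK libraries and 2 control and 2 knockout GMP libraries. GMP library 352 has a title that names the Cre-positive genotype and a genotype field that names the Cre-negative one, so it is unassigned and entered no comparison. Libraries are named by the numbers in their titles. The labels do not say that each library came from a different animal, so the p-values measure the spread between these libraries. Summed coverage was 157.3 to 181.1 M (1e6 reads) in the 6 LSK libraries, with medians of 85 to 103 reads per position, and 95.4 to 109.7 M in the 5 GMP libraries, with medians of 50 to 59. Reads carry no molecular identifiers, so intervals from read counts cover counting error only. The number of C positions with at least 10 reads was 1403302 in all 6 LSK libraries, 1367750 in the 4 assigned GMP libraries and 1293035 in all 10.

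Knockout and control libraries were compared within each cell type by a quasi-binomial logistic model of methylated and unmethylated reads, with an F test and Benjamini-Hochberg adjustment over all features. The dispersion of each feature was moderated by limma 3.58.1 (R 4.3.3, squeezeVar with a trend on log coverage) and kept at 1 or above. Thresholds were an adjusted p under 0.05 with a difference in pooled level of at least 25 percentage points for C positions, 20 for fixed 1000-bp tiles with at least 3 C positions, and 10 for gene ends and gene bodies with at least 5. Differences are knockout minus control. The difference between cell types was tested as the product of cell type and genotype in the same model. Mean levels per library were compared by exact two-sided permutation tests.

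Gene positions came from a RefSeq table of assembly GRCm38.p6, the build of the files. It gives no strand, so a transcription start could not be told from a gene's other end. The planned promoter was replaced by the gene's end with more listed C positions, within 1000 bp, and the gene body by everything farther than 1000 bp from both ends. An alternative promoter from 2000 bp upstream to 500 bp downstream could not be run for the same reason. Several genes can share an end, and each was counted.

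The moderation as fixed before the data were examined includes the many C positions at 0% or 100%, whose dispersion is 0. At single C positions it gave 0.384 prior degrees of freedom in LSK and 0.327 in GMP. A second prior was therefore fitted on features with a pooled level between 5% and 95%. It was chosen after seeing the data, is called the intermediate-level prior, and its counts are given beside those of the fixed test. At GMP C positions its degrees of freedom were not finite. There the test used a spread shared by positions of like coverage, and the spread of each position did not enter. Other alternatives chosen after seeing the data were leaving out 5-Mb windows with group-specific positions, a term for the number of listed Y-chromosome positions, only the 4 LSK libraries with few such positions, the intermediate-level prior without LSK knockout 1333, gene ends within 2000 bp, shared ends counted once, overlaps over positions with control levels of at least 25%, and autosomes only or a term for Y positions for the comparison of control cells. A 5-Mb window was called group-specific when at least 10 C positions, and at least 1% of those common to all libraries, had 20 or more reads in every library of one genotype and none listed in the other.

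The tests were checked on simulated data with the real coverage and control levels, and 200 features lowered by 20, 30, 40 or 50 points. Every feature was given the same spread between libraries, which real features do not share. In simulated LSK tiles (107074) the fixed test passed 58% of the changed tiles at adjusted p under 0.05, and the intermediate-level prior 95.5%. In simulated GMP tiles (107150) these shares were 0% and 92%. At simulated single positions the fixed test passed 0 of 200 changes in LSK (1403302 positions) and in GMP (1367750 positions), against 88 and 39 with the intermediate-level prior. False calls at the minimum difference numbered 0 to 2 in each of these runs. For simulated gene ends (16946 in LSK, 16935 in GMP), the fixed test passed 86.5% in LSK and 0% in GMP. For gene bodies (14411 and 14493) it passed 100% and 92.5%. Of unchanged LSK positions, tiles, ends and bodies, 2.87%, 6.24%, 7.39% and 5.11% had an unadjusted p under 0.05 with the fixed test. Without a minimum difference, its false calls at adjusted p under 0.05 were 0, 1, 6 and 6. With the intermediate-level prior they were 0, 9, 2 and 13. The simulated interaction over 100150 tiles passed 1 of 200. In simulated LSK tiles, limma on logit levels and the quasi-binomial test without moderation passed 0 of 200 and edgeR 39.

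Alternatives fixed beforehand were coverage minimums, an adjusted p under 0.01, other minimum differences and tile sizes, reads thinned to equal depth, strands summed, Fisher's exact test on pooled reads, limma on logit levels with a prior count of 0.5, edgeR 4.0.16 quasi-likelihood on methylated and unmethylated reads, no moderation, spread from all 4 groups, and leaving out each library. A library left alone in its arm was assumed to vary like the others.

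The 14 gene lists, with 374 genes, were fixed before the data were examined: stem cell self-renewal, myeloid differentiation, erythroid and megakaryocyte genes, lymphoid genes, Hox and homeobox genes, developmental transcription factors, leukaemia genes, methylation machinery, RAS, MAPK and cytokine signalling, adhesion and homing, imprinted genes, germline genes, interferon response, and stroma and endothelium. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated one, adjusted over the lists. Genes are named by a rule fixed at the same time: Dnmt3a first, then Dnmt1, Dnmt3b and Tet2; the 10 protein-coding genes with the largest loss and the 10 with the largest gain at gene ends past the threshold with no overlap between groups, without predicted symbols; up to 4 members of each list past the threshold; and the 5 largest tiles each way in each comparison. Genes outside it are said to be chosen after their values were seen. The result of 1 gene that the rule names is not reported here. Figures were drawn with matplotlib 3.10.9.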

Results

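DNA methylation was measured at CpG sites in 11 libraries from sorted bone marrow cells of mice with a floxed Dnmt3a gene. Dnmt3a encodes a DNA methyltransferase that places methyl groups on unmethylated cytosines. Cre-positive animals (knockout) were compared with Cre-negative animals (control) in LSK cells, with 3 libraries of each genotype, and in GMP cells, with 2 of each. Another GMP library, 352, had conflicting genotype labels and was compared with no group. Summed coverage ranged from 157.3 to 181.1 M in LSK and from 95.4 to 109.7 M in GMP (M, 1e6 reads). The series addresses Dnmt3a in myeloproliferation and in the homing and expansion of stem and progenitor cells. Each knockout comparison here asks which regions gain or lose methylation in Cre-positive animals.

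Dnmt3a was examined first (chromosome 12, 3801559 to 3914443, GRCm38). A segment of the gene had fewer than 10 reads at each of its C positions in every knockout LSK library, so these positions were unlisted. The 5 C positions between 3903653 and 3904031 were listed in all 3 control LSK and both control GMP libraries, and 0 of 5 were listed in LSK knockouts 1327, 1333 and 1334. Of 356 positions of the gene listed in all controls, these knockouts listed 347, 348 and 351. The segment was marked by its missing positions, so the 0 of 5 in LSK is not a separate test. Both knockout GMP libraries retained reads there. Library 178 listed 4 of the 5 positions and library 179 listed 5. Relative to flanks of 10 kb, their coverage over the segment was 27.9% and 53.3% of the mean of the GMP controls. The methylation level of the Dnmt3a gene body was 10.7% ± 0.560 (SD, n = 3) in control LSK and 9.99% ± 3.06 in knockout LSK (adjusted p = 0.841). The gene bodies of Dnmt1 and Dnmt3b, the other DNA methyltransferases, and of Tet2, which oxidises methylcytosine, did not pass the threshold in either cell type. Dnmt1 was at 40.4% ± 1.52 in control and 40.8% ± 4.59 in knockout LSK (n = 3 each). Tet2 was at 95.1% ± 0.258 and 91.1% ± 3.15.

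**Figure D1:**
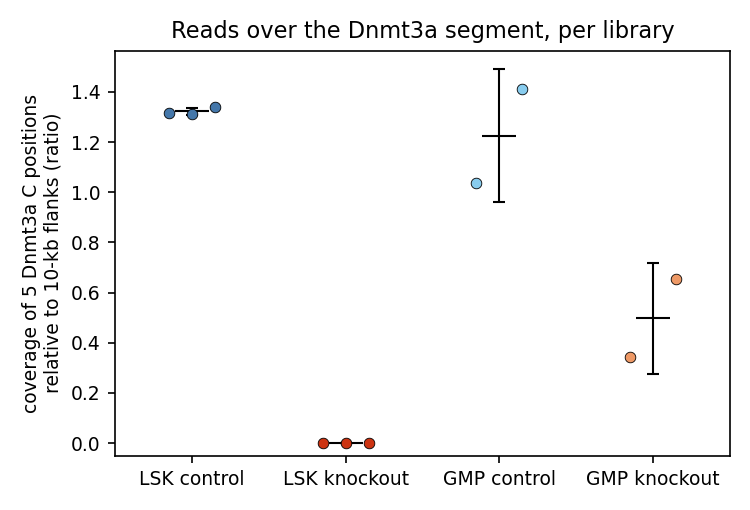
Coverage of 5 C positions of Dnmt3a divided by coverage of its 10-kb flanks (y axis, ratio) in each library of the 4 groups (x axis), with group mean and SD; unlisted positions are drawn at 0. The 3 knockout LSK libraries lie at 0, and the knockout GMP libraries at 0.341 and 0.653, below both control GMP libraries. The positions were marked by being unlisted in knockout LSK.

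Mean methylation was slightly lower in knockout cells of both types. In LSK it was 33.4% ± 0.134 (SD, n = 3) in controls and 32.4% ± 0.113 in knockouts, and it fell by 0.980 points (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow). In GMP it was 34.1% ± 0.0375 (n = 2) and 33.3% ± 0.0777, and it fell by 0.798 points (exact p = 0.333, again the smallest possible). Averaged over both cell types, with genotype permuted within each, the mean fell by 0.889 points (exact p = 0.0167, the smallest of 120 arrangements). With positions weighted by coverage, the difference was -0.720 points in LSK, 0.541 points in GMP and -0.0893 points over both (exact p = 0.85). Over all positions listed for each library, the difference over both cell types was -0.472 points (exact p = 0.333).

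The loss was largest at intermediate levels. C positions were binned by their level in control GMP for the LSK comparison and by control LSK for the GMP comparison, so that no library set its own bin. Knockout LSK differed by -6.16, -7.88 and -5.96 points in the bins of 20 to 40%, 40 to 60% and 60 to 80%, each with no overlap between the 3 libraries of each group (exact p = 0.1 each, the smallest possible). Positions at 80 to 100% fell by 1.37 points, and positions below 20% differed by -0.222 points (exact p = 0.3). In GMP the differences in these 5 bins, from lowest to highest, were -0.234, -3.95, -5.53, -4.60 and -1.09 points (exact p = 0.333 each, n = 2 per group).

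**Figure D2:**
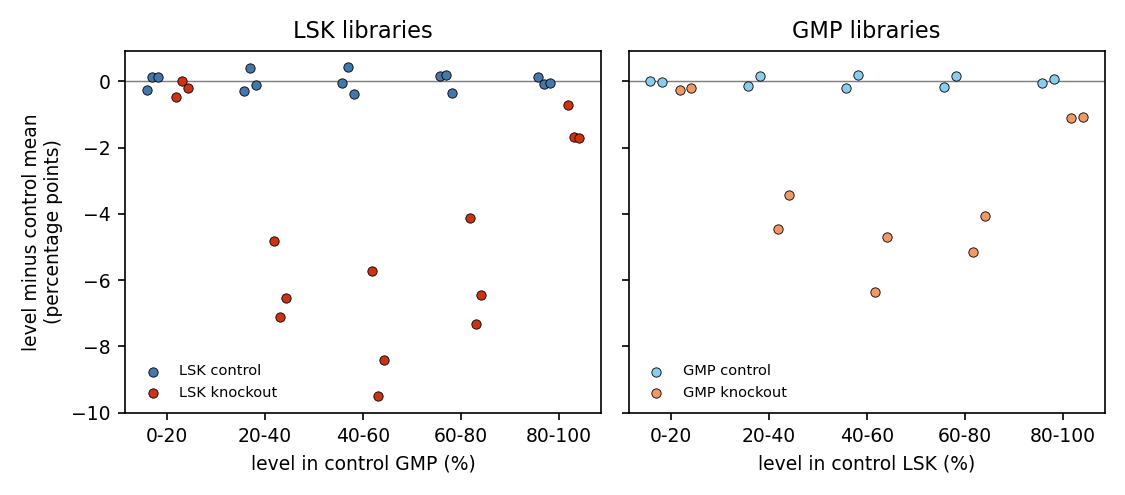
Mean methylation of each library minus the mean of its controls (y axis, percentage points) for C positions binned by their level in control cells of the other cell type (x axis, %), in LSK (left) and GMP (right); each point is 1 library. The deepest points lie in the 40 to 60% bin, where the mean difference was -7.88 points in LSK and -5.53 in GMP.

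In LSK, nearly all tiles that passed the threshold lost methylation. Of 107074 tiles of 1000 bp, 933 fell and 3 rose in the knockout, with a median change of -25.5 points among those that fell. The 5 largest losses lay in Pik3c2b (a class II phosphoinositide 3-kinase), Runx3 (a Runt-family transcription factor), Gnai2 (an inhibitory G-protein subunit), Cbfa2t3 (a transcriptional corepressor) and Dok2 (an adaptor that restrains kinase signalling). The Pik3c2b tile (chromosome 1, 133084001 to 133085000, gene body, 5 C positions, mean coverage 457 reads) was at 86.8% ± 4.91 in controls and 19.4% ± 4.49 in knockouts (n = 3 each, adjusted p = 0.000402). Runx3 (chromosome 4, 135166001 to 135167000, gene body) went from 86.7% ± 3.36 to 24.0% ± 21.2, with 101 reads on average, a call lost in 8 of 20 alternatives. Gnai2 (chromosome 9, 107630001 to 107631000, gene body) went from 74.6% ± 0.969 to 12.8% ± 4.49. Cbfa2t3 (chromosome 8, 122674001 to 122675000, gene body) went from 66.2% ± 3.35 to 11.7% ± 2.56, and Dok2 (chromosome 14, 70777001 to 70778000, within 1 kb of a gene end) from 72.6% ± 8.34 to 18.8% ± 4.13. Their adjusted p ranged from 0.00015 to 0.0115, and all 3 knockout libraries lay below all 3 controls in each.

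**Figure D3:**
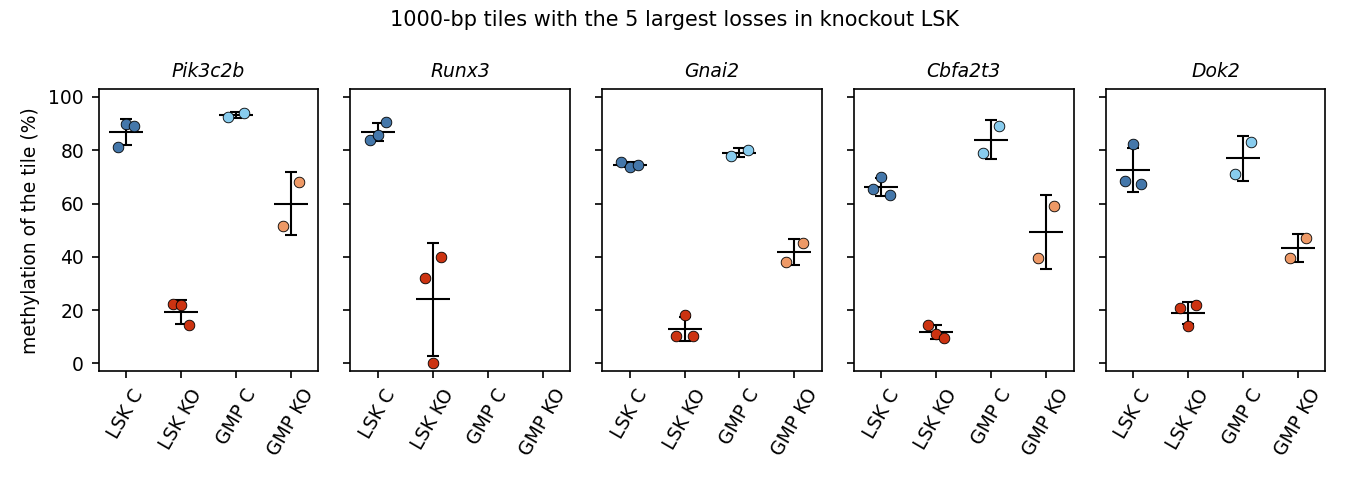
Methylation (y axis, %) of the 1000-bp tiles with the 5 largest losses in knockout LSK, per library (points) with group mean and SD; C is control and KO is knockout. Knockout LSK means lie between 11.7% and 24.0% and knockout GMP means between 41.7% and 60%; the Runx3 tile had too few positions covered in GMP.

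The 3 tiles that rose in LSK were intergenic. The tile nearest Dmrtb1, 8288 bp away, went from 47.2% ± 14.8 to 92.1% ± 8.92 (adjusted p = 0.0206), a call lost in 10 of 22 alternatives. Those nearest Dffb and Epm2a rose by 25.2 and 20.6 points, and both lie in 5-Mb windows where control and knockout libraries list different C positions. Several genes held many lower tiles: Gse1 held 10, Nfix (a nuclear factor I transcription factor) 7, and Runx3 and Pitpnm2 6 each, genes chosen after their values were seen. Lower tiles lay within 1 kb of a gene end more often than the tiles able to fall by that much (16.7% against 10.4%, odds ratio 1.75, 95% interval 1.46 to 2.08, Fisher's exact test, adjusted p = 9.34e-09). They lay outside genes less often (20.8% against 35.0%, odds ratio 0.484, interval 0.411 to 0.569). Tiles of the same gene, such as the 10 in Gse1, are not independent in these tests. Whether control level or coverage accounts for the shares was not tested. The tile counts depend on the test: limma on logit levels, edgeR and the test without moderation passed 0 tiles, and the intermediate-level prior passed 894, all among the same 936. Without single libraries 384 to 1287 tiles passed: 451, 384 and 457 without controls 1326, 1330 and 1331, and 516 without knockout 1334.

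At gene ends, 124 of 16946 genes fell and 0 rose in knockout LSK, and 1841 had an unadjusted p under 0.05. These ends formed 101 separate regions. The intermediate-level prior passed 33 genes in 20 separate regions, and without control 1326, 1330 or 1331 or knockout 1333 or 1334 the count was 47, 39, 40, 62 and 38. With that prior and without knockout 1333 together it was 0. Among protein-coding genes, a large loss was at an end shared by the protocadherin-gamma genes Pcdhga5, Pcdhga6, Pcdhga7, Pcdhga12, Pcdhgb1, Pcdhgb2, Pcdhgb4, Pcdhgb6, Pcdhgb7 and Pcdhgc5, genes that encode neuronal adhesion proteins (chromosome 18, near 37840870 to 37842870). This shared end went from 65.6% ± 6.73 to 25.5% ± 2.51 (n = 3 each, adjusted p = 0.003). The genes rest on the same 11 C positions there. Their other ends lie apart, between 37680272 and 37819546, and without strand the shared end cannot be taken for a promoter. Among gene bodies, 262 of 14411 fell and 1 rose. The body count was 91, 79 and 79 without controls 1326, 1330 and 1331, 476 without knockout 1327 and 56 without knockout 1334.

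Bodies of stem cell genes and ends and bodies of Hox genes were lower as lists in knockout LSK at camera's preset correlation, and not with an estimated correlation. Of 28 self-renewal genes with a measured body, the body of Hlf, a stem cell transcription factor, fell from 49.8% ± 4.76 to 25.1% ± 1.19 (n = 3 each, adjusted p = 0.00197). The bodies of Gata2, Esam and Msi2 also had an adjusted p under 0.05, with differences of -8.13, -6.38 and -7.16 points that were below the 10-point minimum. The other 24 did not pass, 0 of 23 ends passed, and 6 bodies and 2 ends passed when adjusted over the list alone. The list held 11 lower and 0 higher tiles, in Prdm16, Hlf, Gata2, Runx1 and Msi2. The Prdm16 tile with the largest loss was at 60.8% ± 3.39 in controls and fell by 47.5 points. All 4 Prdm16 tiles lie in a window of chromosome 4 (150 to 155 Mb) where control and knockout LSK list different positions. In the Hox and homeobox list, 2 of 37 ends fell, those of Hoxa5 (51.6% ± 7.5 to 22.2% ± 4.53, adjusted p = 0.0134) and Hoxa6, whose ends overlap, and 1 of 26 bodies, that of Hoxb1, from 36.8% ± 6.36 to 21.5% ± 4.04, a call lost in 7 of 14 alternatives. The end of Hoxd12 and the bodies of Hoxa3 and Hoxb3 had an adjusted p under 0.05 with differences below 10 points. The Hoxa3 body holds 2 lower tiles (chromosome 6, 52203001 to 52205000) that overlap the ends of Hoxa5 and Hoxa6. These members therefore share C positions and are not separate evidence in the counts and list tests. Adjusted over the list alone, 7 ends and 7 bodies passed. As a list, Hox ends were lower than other genes (camera, adjusted p = 9.33e-06; adjusted p = 0.254 with an estimated correlation), and so were Hox bodies (adjusted p = 0.0388; adjusted p = 0.739 with an estimated correlation) and self-renewal bodies (adjusted p = 0.0403; adjusted p = 0.739 with an estimated correlation).

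Developmental transcription factors had lower ends and bodies as a list (adjusted p = 0.0431 and 0.0403; adjusted p = 0.589 and 0.739 with an estimated correlation), while 0 of 39 ends and 0 of 35 bodies passed the single-gene threshold by the limma-moderated test; adjusted over the list alone, 1 end and 0 bodies had an adjusted p under 0.05. The end of Pax7 had an adjusted p under 0.05 with a smaller difference. The shifts of this list were small and at low levels. Its mean went from 3.73% ± 0.445 to 3.05% ± 0.293 at ends and from 9.06% ± 0.0600 to 8.09% ± 0.559 in bodies (n = 3 each). Camera compared logit levels, where small shifts near 0% weigh more. Ends of myeloid differentiation genes were lower as a list (adjusted p = 0.0431; adjusted p = 0.395 with an estimated correlation), with 0 of 17 past the threshold by the limma-moderated test and 1 adjusted over the list alone, and 1 of 13 bodies fell. That body was of Gfi1, a transcriptional repressor in stem and myeloid cells, from 21.6% ± 1.77 to 3.61% ± 0.856 (adjusted p = 0.000871). Lower tiles also lay in Irf8 and Spi1, transcription factors of the myeloid lineage. Of the leukaemia genes 1 of 31 bodies fell, that of Mn1 (48.6% ± 6.40 to 30% ± 3.13), and 5 lower tiles lay in Mn1, Gata2, Runx1 and Dnmt3a. Genes of stroma and endothelium showed a lower end of Tagln, a smooth muscle actin-binding protein (53.9% ± 1.88 to 29.5% ± 6.65), and a lower body of Pdgfrb (89.2% ± 1.16 to 75.0% ± 7.55, a call lost in 5 of 14 alternatives), 1 of 7 ends and 1 of 12 bodies. Of the germline list 1 of 12 bodies fell, that of Pou5f1, from 24.7% ± 4.05 to 13.7% ± 2.25, a call lost in 10 of 14 alternatives. With the intermediate-level prior the ends of Tagln, Hoxa5 and Hoxa6 and the body of Pou5f1 had adjusted p of 0.116, 0.0928, 0.0968 and 0.0516. The calls at the ends of Tagln, Hoxa5 and Hoxa6 were each lost in 8 of 16 alternatives.

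No end or body passed in the erythroid and megakaryocyte, lymphoid, methylation machinery, RAS, MAPK and cytokine, adhesion and homing, imprinted or interferon lists, and their camera tests did not pass. Lower tiles lay in Itga2b and Zfpm1 of the erythroid and megakaryocyte list, Notch1 of the lymphoid list, Tet1 and Dnmt3a of the methylation machinery, Socs2 of the cytokine list, Itga6 of the adhesion list and Kcnq1 of the imprinted list. The developmental, germline and interferon lists held none. The body of Jak3, of the cytokine list, had an adjusted p under 0.05 with a difference of -5.96 points. Adjusted over the list alone, the adhesion, lymphoid and germline lists had 1 lower end each and the stroma list 2, and the leukaemia and myeloid lists had 3 lower bodies each and the interferon, cytokine, germline and stroma lists 1 each. In 16 of the 56 list tests in both cell types the median, the mean and camera's direction did not have the same sign, in 0 of the 8 that passed.

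At single C positions in LSK, the limma-moderated test passed 0 of 1403302 positions, with 71469 at an unadjusted p under 0.05. That test passed 0 of 200 simulated changes of up to 50 points. The intermediate-level prior passed 1978 lower and 29 higher positions, and Fisher's exact test on pooled reads, which ignores the spread between libraries, 11200 and 757. Knockout library 1333 stood apart from the other LSK libraries: 45574 C positions were listed in it alone, against 45 to 175 in each of the others. Without it and with the intermediate-level prior, 3151 positions were lower and 87 higher.

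In GMP, the bodies of Kcnn4, a calcium-activated potassium channel, and Ssbp4 lost methylation in the knockout. Kcnn4 (chromosome 7, 24370827 to 24384211) went from 75.3% ± 0.0595 (SD, n = 2) to 47.1% ± 1.11 (n = 2, adjusted p = 0.00757), and Ssbp4 (chromosome 8, 70598486 to 70607386) from 76.6% ± 0.164 to 56.5% ± 0.382 (adjusted p = 0.0475). Both bodies were also lower in knockout LSK, by a change of -29.2 points for Kcnn4 and -30.6 for Ssbp4. The bodies of Srd5a3, a steroid reductase gene, and Gm36357, a lncRNA, rose from 57.6% ± 4.37 to 90.9% ± 1.27 and from 54.2% ± 0.243 to 95.1% ± 1.12 (adjusted p = 0.0175 each). Both lie on chromosome 5 in windows where the GMP control and knockout libraries list different C positions. These 4 were chosen after their values were seen; they are all of the 14493 bodies that passed. Without control 349 or knockout 178 or 179 the count was 0.

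The limma-moderated test passed 0 of 107150 tiles in GMP (9338 at an unadjusted p under 0.05), 0 of 16935 gene ends (1508) and 0 of 1367750 C positions (17788). By limma on logit levels, edgeR and the test without moderation, 0 tiles passed too. With the intermediate-level prior, 266 tiles were lower and 29 higher, 36 ends lower and 1 higher, 110 bodies lower and 10 higher, and 266 C positions lower and 107 higher. The calls at C positions rest on a spread shared over positions, so they do not measure the spread between libraries at each position. With the spread taken from all 4 groups, 85 tiles were lower and 10 higher, and Fisher's exact test on pooled reads passed 783 and 105. Of the tiles found with the intermediate-level prior, the largest losses were in Plac8, near Dmrtb1 and in Egfl7 (-65.7, -59.1 and -57.9 points) and in Adpgk and Galnt2 (-55.3 and -49.9). The largest gains were near Scpep1 (52.1 points), in Srd5a3, Gm36357 and Thsd4 (45.1, 40.9 and 40.4) and near Ptpn13 (38.6). Those in or near Plac8, Adpgk, Srd5a3, Gm36357, Thsd4 and Ptpn13 lie in windows with group-specific positions. There were 28 such windows with 5.97% of the tested C positions. They held 36.8% of the lower and 79.4% of the higher positions found with that prior, and a new fit without the windows passed 128 lower and 19 higher positions. Among the 14 lists, Hox and self-renewal bodies were lower in knockout GMP (camera, adjusted p = 0.0388 each; adjusted p = 0.629 each with an estimated correlation). Their single members passed in 0 of 26 and 0 of 28 cases over all genes, and in 5 and 6 adjusted over the list alone.

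Tiles lower in knockout LSK were compared in GMP, whose libraries are different ones. Of the 933 tiles, 897 were measured in GMP, and 860 of these (95.9%) were lower in knockout GMP, against 62.9% of the 77501 background tiles. Their mean level was 63.1% ± 0.421 in control and 35.6% ± 3.08 in knockout LSK (n = 3 each), and 63.8% ± 0.279 in control and 47.8% ± 4.32 in knockout GMP (n = 2 each, exact p = 0.333, the smallest possible). Knockout GMP libraries 178 and 179, which retained reads over the Dnmt3a segment, were at 44.7% and 50.8%. These tiles were chosen for their loss in LSK. Conversely, the 257 tiles lower in GMP with the intermediate-level prior and measured in LSK had a median change of -28.4 points in GMP and -23.5 in LSK. Gene ends lower in LSK went from 61.4% ± 0.259 to 47.7% ± 3.97 in GMP, and bodies from 66.7% ± 0.209 to 58.2% ± 2.10.

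**Figure D4:**
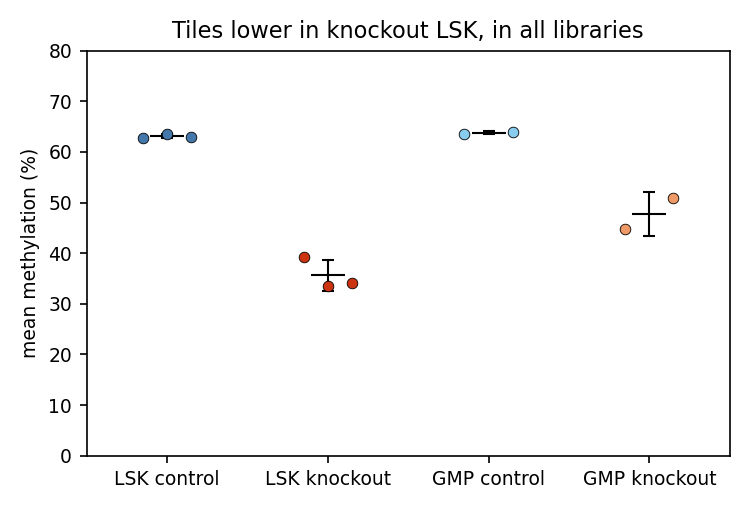
Mean methylation (y axis, %) over the 897 tiles lower in knockout LSK and measured in GMP, per library (points) in the 4 groups (x axis), with group mean and SD. Knockout GMP libraries, at 44.7% and 50.8%, lie between the knockout LSK libraries and the controls.

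With no C position past the fixed test, the planned overlap of lower positions has no value. With the intermediate-level prior, 90 positions were lower in both LSK and GMP. The GMP list rests on a spread shared over positions. Over the 461588 positions with a control level of at least 25% in both cell types, where independent lists would share 0.874, the odds ratio was 182 (95% interval 136 to 240, Fisher's exact test; positions are not independent). No position was higher in both, and 19 positions past the threshold in both moved in opposite directions. The difference of the knockout effect between cell types was tested directly. It passed at 0 of 1293035 positions (48638 at an unadjusted p under 0.05, and 59 past the threshold with the intermediate-level prior, 79.7% of them in GMP windows with group-specific positions) and at 3 of 100150 tiles, in Nphp4, Plekhg5 and Srd5a3 (adjusted p = 0.0474 each). All of these tiles lie in windows with group-specific positions, and with the intermediate-level prior 0 tiles passed (4342 at an unadjusted p under 0.05).

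Control GMP and control LSK libraries differed at tiles that included some in genes of the myeloid lineage. Whether these genes held more such tiles than other genes was not tested. The cell types come from separate library series, so cell type and series cannot be told apart. Of 104839 tiles, 809 were lower and 118 higher in control GMP. In the myeloid differentiation list, 7 tiles were lower in GMP, in Mpo (myeloperoxidase), Ctsg (cathepsin G), Cebpe, Spi1 and Irf8, and 1 was higher, in Gfi1. The Mpo tile at 87799001 to 87800000 of chromosome 11 was at 90.9% ± 2.11 in LSK (n = 3) and 51.2% ± 1.96 in GMP (n = 2), Ctsg at 90.4% ± 0.989 and 52.1% ± 5.49, and a Cebpe tile at 70.8% ± 2.09 and 27.6% ± 1.18. The Gfi1 tile was at 31.5% ± 1.96 in LSK and 70.4% ± 2.74 in GMP. Tiles in Itgb2, Flt3, Etv6 and Dntt were lower in GMP, and tiles in Hoxa3 and Zfpm1 higher. The largest losses with an overlapping gene lay in Uggt1 (89.9% ± 2.42 to 5.21% ± 0.131), Sema4d, Angptl8, Lrpap1 and Sec22b, and the largest gains in Ube2ql1 (10% ± 1.59 to 85.8% ± 10.5), Pik3r1, Dcdc2c, Egfl7 and Gm42252. The cell types were sequenced to different depth, and the GMP libraries list 1226 to 1326 positions of the Y chromosome while 4 of the 6 LSK libraries list 211 to 229, and 1 control LSK library, 1326, lists 1470. With a term for many or few Y positions, which compares 1326 with the 2 GMP controls, 83 tiles were lower and 8 higher in GMP, and 879 of the 927 tiles differed by at least 20 points in the same direction. Library 1326 and the 2 GMP controls also helped choose the 927 tiles, so this agreement in direction and size is not independent of that choice. In a new fit on autosomes only, 861 tiles were lower and 138 higher. Control LSK and GMP libraries listed different positions in 100 of 501 autosomal 5-Mb windows, which hold 89 of the called tiles (9.60%, against 10.9% of the tested tiles), Ube2ql1, Pik3r1, Dcdc2c, Gm42252 and Etv6 among them. Without LSK control 1330 or 1331 or GMP control 346 or 349 the count was 289, 293, 300 and 271.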

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

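All tests of explanations in this part were chosen after the result was seen, apart from the counts over other splits of tiles, gene ends and gene bodies. The test for a sample far from its own group needs 4 libraries and was not applied to groups of 2 or 3. The first 5 tiles appear here because the knockout effect differed between cell types by its test, or because it had opposite directions in them.

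The difference of the knockout effect, GMP minus LSK, passed its test at tiles of Nphp4 (-33.5 points), Plekhg5 (-23.2 points) and Srd5a3 (47.3 points). In Nphp4, LSK went from 78.2% ± 3.99 to 97.0% ± 2.67 and GMP from 96.8% ± 0.621 to 80.6% ± 3.69. In Srd5a3, LSK went from 82.3% ± 4.07 to 80% ± 4.28 and GMP from 43.1% ± 3.33 to 88.5% ± 2.15. At a tile nearest Dmrtb1 every knockout LSK library lay above the controls while knockout GMP differed by -59.1 points. At a tile in Pik3c3, LSK went from 43.2% ± 8.21 to 15.4% ± 6.95 and GMP differed by 37.1 points (0.501% ± 0.708 to 38.5% ± 52.7). In Pik3c3 the SD of knockout GMP exceeds its mean, so the change is not shared evenly by the 2 libraries. At both of these tiles the moderated test of the difference between cell types had an adjusted p of 0.0993 for the tile nearest Dmrtb1 and 0.509 for the tile in Pik3c3, so neither passed.

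Higher methylation in knockout GMP concentrated in the windows where the genotypes list different C positions. Inside them, higher positions per 10000 tested were 60.8 times as frequent as outside, with the intermediate-level prior. The concentration was weaker without that prior. Positions higher by at least 25 points with no overlap between groups, whatever their p, were 43.1 per 10000 inside and 15.7 outside. They numbered 352 inside and 2016 outside. Depth argues against itself as the source, since knockout coverage relative to control at these positions was 1.04 times that over all tested positions. A candidate explanation is stretches of another strain's genome that differ between the control and knockout animals. The windows lie on chromosomes 1, 4, 5, 6, 7, 9, 12, 13 and 17. Where such stretches would come from was not tested. A knockout effect of similar size in LSK is argued against: at 78 of these positions measured in both, the median difference was 66.2 points in GMP and 6.88 points in LSK (bootstrap 95% interval 3.65 to 10.2). The 78 positions were chosen for a gain of at least 25 points in GMP, which raises the GMP value. The interval resamples positions, not libraries, and its upper limit of 10.2 lies below that minimum. An effect limited to GMP was not tested.

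LSK knockout 1333 had 271 C positions below 20% where every other LSK library was above 80%. An expanded clone would move both strands of a CpG together, and the tables argue against it as the source of these positions. At 321 C positions far from every other LSK library, below 20% against above 80% or the reverse, the other strand of the same CpG differed by a median of -1.90 points in that direction (bootstrap 95% interval -2.48 to -1.15), and by at least 40 points at 7 of them. Few template molecules amplified in library preparation remain a candidate source.

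Knockout GMP libraries held reads over the Dnmt3a segment. DNA of the GMP control animals in these libraries is argued against by C positions inside the windows that had at least 100 reads in both controls and were unlisted in the knockout, 104 in library 178 and 61 in library 179, where that share of control DNA would have left them listed. Inside the windows 13731 positions had that depth in both controls. The windows were chosen for positions listed in 1 genotype only. Elsewhere 18 and 13 of 214594 positions of that depth were unlisted in 178 and 179. Cells whose segment was not deleted, or cells of other animals, may account for the reads. The library with more of the segment, 179, was 6.10 points higher over tiles lower in knockout LSK, and 1 pair of assigned libraries is too few to decide whether the 2 values go together. The unassigned GMP library 352 listed 0 of the 5 segment positions. Over 1920 C positions lower in knockout LSK it was at 18.9%, with 178 at 39.3% and 179 at 48.4%. These libraries have the same order in both values. Both GMP controls listed all 5 segment positions and were at 67.4% and 67.5% over the same 1920 positions. These values argue against a Cre-negative genotype for 352, whose labels conflict and which entered no comparison.

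The 6 LSK libraries split into groups of 3 in 10 ways, the real one included, too few for a share under 0.05. The real split gave 936 tiles, 124 gene ends, 263 gene bodies and, with the intermediate-level prior, 2007 C positions, and the highest of the other splits gave 0 in each. In each case 1 of the 10 splits, the real one, gave a count as large.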

How the results depend on the processing

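Of 175 alternative values for the main results, 116 kept direction and side of the threshold, or stayed within 1.5 times the count. Of these, 20 were for LSK positions, 16 for GMP positions, 15 for GMP tiles and 9 for GMP ends. Those counts were 0 under the fixed test, which passed no simulated change there, so they say little about stability. LSK tiles stayed in 13 and moved in 11, LSK ends 7 and 9, LSK bodies 8 and 6, and GMP bodies 1 and 8. Causes were not tested unless named. No paired analysis was possible because the groups share no library numbers. The promoter from 2000 bp upstream to 500 bp downstream was not run, and overlaps and shares of lower C positions had no value under the fixed test. For 18 single genes and tiles past the threshold, with overlapping ends counted once, 234 of 317 alternative values stayed past it, 83 lost it and 0 reversed. For 12 values of Dnmt1, Dnmt3a, Dnmt3b and Tet2 that did not pass, 146 of 146 stayed so.

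Chosen after seeing the data were the intermediate-level prior, the windows and the Y-position subset. With the intermediate-level prior, C positions past the threshold were 2007 in LSK (98.6% lower) and 373 in GMP (71.3% lower), and with group-specific windows also left out 1950 (99.2% lower) and 147 (87.1% lower). Without LSK knockout 1333 and with that prior there were 3238 (97.3% lower). That prior gave 33 LSK gene ends, or 30 without the windows and 0 without knockout 1333. In GMP it gave 295 tiles, 37 ends and 120 bodies, and without the windows 214, 37 and 113. It gave 59 interaction positions and 0 interaction tiles, and odds ratios for the overlap of 381 over all positions, 182 over positions with control levels of at least 25%, 356 with lists at 10 points and 343 at coverage 20. Leaving out the windows alone gave 1 GMP body and 0 interaction tiles. The 4 LSK libraries with few Y positions, a smaller sample, gave 389 tiles, and a term for Y positions, which leaves 1 LSK library against 2, gave 91 tiles between control cells.

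Fisher's exact test on pooled reads, which takes no spread between libraries, gave 11957 LSK positions (93.7% lower), 10652 GMP positions (81.1% lower) and 888 GMP tiles. The LSK tile count was 0 without moderation, 0 with limma on logit levels and 0 with edgeR, 494 at an adjusted p under 0.01, 2002 at a 10-point minimum and 578 in tiles of 5000 bp, which are fewer. At an adjusted p under 0.01 there were 41 LSK ends, 84 LSK bodies and 1 GMP body. Spread from all 4 groups gave 95 GMP tiles, and coverage 20 gave 2 GMP bodies. Lists passing camera went from 8 to 0 with an estimated correlation.

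Leaving out each library in turn gave 384 to 1287 LSK tiles, 38 to 160 ends, 56 to 476 bodies, 0 to 3 GMP bodies and 271 to 986 tiles between control cells, while the mean difference stayed between -1.05 and -0.924 points in LSK and between -0.852 and -0.743 in GMP. Weighted by coverage, the GMP mean difference reversed to 0.541 points and that over both cell types was -0.0893; over all listed positions the latter was -0.472. In GMP, with 95.4 to 109.7 M summed reads against 157.3 to 181.1 M in LSK, 2 libraries per group leave 2 residual degrees of freedom, and the fixed test passed 0% of simulated GMP tile changes. With the same libraries it passed 92.5% of simulated GMP body changes, but bodies had a median coverage of 1208 reads against 337.5 for tiles. On the same simulated tiles the intermediate-level prior passed 92% of changes. Every simulated feature had the same spread, which favours a prior that shares it. In these simulations the 0% for tiles depended on the prior. Whether size and depth limit the test in the real GMP libraries cannot be told from them.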

Other observations

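Bodies and ends outside the naming rule, chosen after their values were seen, were among those with lower methylation in knockout LSK. The ends of Cabcoco1 (49.0% ± 4.54 to 12.4% ± 5.63, n = 3 each), Rps6ka4, a stress-activated kinase (82.0% ± 3.05 to 45.8% ± 6.49), Alpk3 (77.5% ± 3.38 to 42.0% ± 5.00) and Cdhr3 (49.5% ± 2.22 to 15.8% ± 2.75) fell, each with an adjusted p of at most 0.00658. Genes with 4 lower tiles included Ephb2, an ephrin receptor, Smad6, an inhibitor of BMP signalling, and Ltbp3, which binds latent TGF-beta, with largest losses of -46.9, -43.9 and -44.9 points. Zbtb16, a transcription factor of progenitors and innate-like lymphocytes, held 3, with a largest loss of -36.9 points.

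The Gfi1 tile that was higher in control GMP than in control LSK (70.4% against 31.5%, over 53 C positions) differed by -26.8 points in knockout LSK. The Gfi1 gene body was at 36.7% ± 1.36 in control and 22.4% ± 0.817 in knockout GMP (n = 2 each), with an adjusted p of 0.0802, so it did not pass there. Over the 39 C positions listed in all 4 GMP libraries, the tile itself was at 74.0% ± 13.5 in control and 39.0% ± 0.214 in knockout GMP, past the threshold with the intermediate-level prior (adjusted p = 0.00214) and not with the fixed test. It lies in a window where the GMP genotypes list different positions.

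The GMP library 352, whose labels conflict, had these values. It listed 0 of the 5 C positions of the Dnmt3a segment, and its mean level over 1265520 positions listed in all 11 libraries was 31.5%, where the GMP controls were at 32.9% each and knockouts 178 and 179 at 32.0% and 32.2%. Over 1920 positions lower in knockout LSK with the intermediate-level prior, it was at 18.9%, the controls at 67.4% and 67.5%, and knockouts 178 and 179 at 39.3% and 48.4%.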
